A study of Mus musculus with 56 samples.

How the data were processed

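Peak lists of 46 libraries and 24 pooled or per-condition lists were used, for 56 samples. The 10 samples without a list of their own include both ChIP-seq inputs and the EP300 and HDAC2 libraries of the preadipocytes, which were used as 1 list per Runx2 form. Per the submitters' processing notes, reads were handled with fastp, Bowtie2, SAMtools and Picard, and peaks were called with MACS2 against mm39, with no versions stated. No reads were aligned and no peaks were called here. The per-library lists were called on each library by itself, while names of the pooled lists point to merged libraries, so pooled calls draw on more reads. No file was identical to another in its peaks.

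The authors' deposited lists give for each peak a fold enrichment over the background of the peak caller, and this ratio was compared only within a list. The -log10 p and -log10 q values in the deposited lists come from the peak caller, and the lowest -log10 q was 1.30. The score in the deposited lists equals 10 times the -log10 q, cut to a whole number, and served only to rank the best peaks of a list. The counts in the deposited HA lists are whole numbers per listed peak, and those lists hold only peaks with a count of at least 50 and a fold of at least 4. The authors' table of changed HA sites has a column headed Fold, read here as a log2 fold of full-length over IDR-deleted Runx2. These values are not the plain differences of the concentrations in that table and are smaller in size at the sites named below. That table also gives an FDR. The p-value and the column read as FDR in the authors' deposited EP300 and HDAC2 lists have no header and were read from their range. Each of these lists has 4 columns of per-library values that were not used here, because their unit is not named.

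Peaks on chromosomes 1 to 19, X and Y were kept, which left out 4 to 57 peaks per library. Peak starts were converted to positions counted from 1, and all positions are in mm39. For each comparison of 4 libraries, overlapping whole peaks (at least 1 bp) were merged into regions. A region was gained when both altered libraries and neither control had a peak, and lost in the reverse case. The balance was the log2 of gained over lost with 0.5 added to each. The same ratio was taken for the 4 pairs of 1 altered and 1 control library, where a region needs a peak in 1 library and none in the other. The SD of these pairs served only to judge whether the ratio moved between settings. The 2 other divisions of the same 4 libraries were treated alike. With equal list lengths, each list was trimmed to the shortest of its comparison, best -log10 p first. For coverage of sites, the trimming was over the 6 libraries of an antibody.

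Runx sites were the ChIP-seq peaks of preadipocytes, the HA-Runx2 peaks found in both libraries, and the Runx peaks of wild-type iWAT found in both libraries. Occupancy of gained and lost regions was compared with each other and with regions found in all 4 libraries. A further setting kept only those of a width between percentiles 5 and 95 of the changed regions. Odds ratios have 95% Woolf intervals and Fisher's exact p. Coverage was the percentage of sites with a peak in a library. Differences between groups were averaged over the 3 antibodies and tested by exact permutation of libraries within antibodies, over 216 arrangements, with Benjamini-Hochberg adjustment over 18 tests. Overlap of Runx lists was compared with 100 random placements of the peaks, made with numpy up to the largest listed coordinate of each chromosome in place of a shuffling tool with chromosome sizes. Regions changed with both factors were compared with 100 simulations of unchanged groups against the same controls, and with independent lists when each factor had 1 control library, in both assignments, a choice made after the data were seen. Named windows were the 3 windows of 100 kb with the most net gained and the 3 with the most net lost regions per comparison, a rule chosen after the data were seen. Peaks were named from the 5 best of a list by this score.

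The gene table at hand is of GRCm38 and the lists are of mm39, so no gene was assigned to a region. No genome sequence was used here, so motifs were not searched. The counts of HA peaks were not tested, because each library has counts for its own peaks only. The second HDAC1 library of Runx2 overexpression names HDAC2 in its antibody field and was kept in the group of its title.

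Python 3.11.15 was used with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. A self-test drew presence of peaks in the 55779 regions of the Runx2 HDAC1 comparison 20 times without an effect and planted 200 gained regions with a Runx2 peak, detected in 90% of altered and 5% of control libraries. It recovered 74.2% of the planted regions, against 73.1% by calculation. Without an effect the odds ratio of Runx peaks in gained against lost regions had a median of 1.07 (range 0.768 to 1.39). The draws without an effect gave means of 4254 gained and 969 lost regions. In them each region kept its share of peaks over all real libraries of the comparison. These counts can therefore be too high and do not show the part of list lengths alone.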

Results

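The series mapped RUNX1 and RUNX2, transcription factors of the runt family, and chromatin proteins in mouse fat cells and fat tissue. Its title concerns deletion of either factor in adipocytes and the formation of beige fat, the heat-producing cells that arise in white fat. H3K27ac, a histone mark of active promoters and enhancers, and the histone deacetylases HDAC1 and HDAC2 were profiled by CUT&Tag, which cuts and tags DNA where an antibody binds. Mature brown adipocytes were compared as control, Runx1-overexpressing and Runx2-overexpressing cells, with 2 libraries per antibody and group. Inguinal white adipose tissue (iWAT) was compared as wild type and as tissue with an Adipoq-cre knockout of Runx1 or Runx2, an adipocyte-directed deletion, also with 2 libraries per antibody and group. Wild-type iWAT had 2 further libraries each for Runx1 and Runx2. Brown preadipocytes gave ChIP-seq lists for Runx1 and Runx2, EP300 and HDAC2 lists with full-length or IDR-deleted Runx2, and HA-tag lists of both Runx2 forms. EP300 is a histone acetyltransferase, and IDR is the label's name for the part removed from Runx2.

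Peak lists were used for 46 single libraries, and 24 more lists stood for whole groups. CUT&Tag libraries held between 13098 and 64927 peaks, with 13098 to 35580 in the adipocytes and 14806 to 64927 in iWAT. The ChIP-seq lists held 11365 peaks for Runx1 and 8832 for Runx2. Read totals per library are unknown from peak lists, so the number of peaks stood in for depth. Only the 4 HA libraries also had counts in their listed peaks, from 3578311 to 4150320. Between 42.4% and 91.9% of a library's peaks overlapped a peak of the other replicate. The ratio between replicate list lengths was largest in wild-type iWAT H3K27ac, with 32872 and 64927 peaks, and in control adipocyte HDAC2, with 26624 and 13098 peaks. The labels do not say whether replicates were separate cultures or animals, so the p-values may measure technical spread. All positions are in mm39.

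The first comparison asked how far Runx1 and Runx2 occupied the same places. In preadipocytes 4689 of 11361 Runx1 ChIP-seq peaks (41.3%) overlapped a Runx2 peak, and 53.4% of the 8822 Runx2 peaks overlapped a Runx1 peak. Random placement of the same peaks gave means of 0.362% and 0.467%. In iWAT between 44.7% and 64.7% of Runx1 peaks overlapped Runx2 peaks over the 4 pairs of libraries, and 67.7% to 82.7% of Runx2 peaks overlapped Runx1 peaks. Replicates of the same factor in iWAT shared 58.3% to 84.4% of their peaks, over lists of unequal length. Among the 5000 best peaks of each list the factors shared 69.4% to 70.5%, and replicates of the same factor 75.1% to 80.2%. High overlap was not limited to Runx. Wild-type H3K27ac, HDAC1 and HDAC2 libraries had a peak at 90.8%, 80.3% and 70.6% of the iWAT Runx1 sites on average. Those 15818 sites were found in both Runx1 libraries, so these percentages cannot be set directly against those over all peaks of a library. Preadipocyte and iWAT sites were less alike among the 5000 best peaks of each list. There 19.4% and 19.2% of preadipocyte Runx1 peaks overlapped iWAT Runx1 peaks, and 12.2% and 11.6% for Runx2. The 2 factors in preadipocytes shared 48.6% and 48.8%. Over all peaks, in lists of unequal length, iWAT Runx1 peaks covered 41.8% and 35.4% of the preadipocyte Runx1 sites. iWAT Runx2 peaks covered 21.3% and 23.0% of the preadipocyte Runx2 sites. The assays also differed, with CUT&Tag in iWAT and ChIP-seq in preadipocytes. HA-tagged Runx2 covered 78.6% of the Runx2 ChIP-seq peaks in each library.

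The strongest Runx1 ChIP-seq peak lay on chromosome 19 from 5843118 to 5846495, with a fold over background of 184. Runx2 had its fourth-ranked peak there, from 5843133 to 5845709, with a fold of 43.4. Its first-ranked peak was on chromosome 13 from 21510350 to 21512123, with a fold of 90.9. In iWAT the pooled Runx1 and Runx2 lists both held a peak on chromosome 10 among their 5 best, from 80457824 to 80458633 for Runx1 and from 80457842 to 80458628 for Runx2, with folds of 15.7 and 14.5. A peak there was present in all 46 libraries with a list of their own, so it was not specific to Runx. The ChIP-seq lists had no replicate.

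Runx1 or Runx2 overexpression was compared with control adipocytes to ask where the marks and deacetylases changed. Peaks of overexpressing adipocytes covered more of the places where preadipocytes carried Runx. Averaged over the 3 antibodies, control libraries had a peak at 29.4% of Runx2 ChIP-seq sites, Runx1-overexpressing libraries at 42.6% and Runx2-overexpressing libraries at 53.2%. HDAC1 coverage of these sites rose from 31.2% ± 0.41 (SD, n = 2) in controls to 45.5% ± 5.7 with Runx1 and 59.6% ± 1.4 with Runx2. HDAC2 coverage rose from 26.2% ± 7.3 to 43.4% ± 6.8 and 52.8% ± 1.9, each with n = 2. H3K27ac coverage rose from 30.6% ± 6.3 to 38.8% ± 3.0 and 47.3% ± 7.1, each with n = 2. Both overexpressing libraries lay above both controls for each of the 3 antibodies, with either factor.

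An exact permutation test within the 3 antibodies (two-sided, 216 arrangements, smallest p 0.00926) gave p = 0.00926 for each factor at the Runx2 sites. The Benjamini-Hochberg value over 18 tests was 0.0333 for both. The test treats libraries of different antibodies as independent, which the labels leave open. Runx2 overexpression also covered 10.7 percentage points more of the Runx2 sites than Runx1 overexpression did, higher in both libraries for all 3 antibodies (exact permutation p = 0.00926, adjusted 0.0333). At Runx1 ChIP-seq sites the mean coverage was 44.6% in controls, 54.7% with Runx1 (exact permutation p = 0.0185, adjusted 0.0370) and 62.4% with Runx2 (exact permutation p = 0.00926, adjusted 0.0333). Both Runx1-overexpressing libraries lay above both controls for 2 of the 3 antibodies there. Without the second Runx1-overexpressing HDAC2 library the difference for Runx1 was 8.55 points, with an exact permutation p of 0.0556. At 23912 HA-Runx2 sites coverage rose from 46.2% to 57.0% with Runx1 and 66.6% with Runx2 (exact permutation p = 0.0185 and 0.00926, adjusted 0.0370 and 0.0333).

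A set of 56306 preadipocyte EP300 peaks without any Runx peak served for comparison. A peak with either Runx2 form was enough, and the set was not matched to the Runx sites in peak strength. Its coverage in controls was far lower than that of the Runx sites. Changes in points therefore cannot be set directly against those at Runx sites. Coverage of these was 10.6% in controls, 10.9% with Runx1 and 11.3% with Runx2, and neither difference passed the test (exact permutation p = 0.833 and 0.741). These means hide opposite movements of single antibodies with Runx2. HDAC1 coverage of the EP300 set rose from 10.85% to 14.0%, with both libraries (13.1% and 14.8%) above both controls (10.8% and 10.9%), and HDAC2 coverage rose by 1.90 points, while H3K27ac coverage fell from 13.1% to 10.2%. With lists trimmed to equal lengths, coverage of the EP300 set fell by 1.28 points with Runx1 and fell by 1.80 points with Runx2 (exact permutation p = 0.00926 for each). A list of fixed length that gains Runx sites must lose other peaks, so part of this fall is forced. Runx2-site coverage with equal lengths was still 9.47 and 18.0 points above control (exact permutation p = 0.00926 for each).

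**Figure D1:**
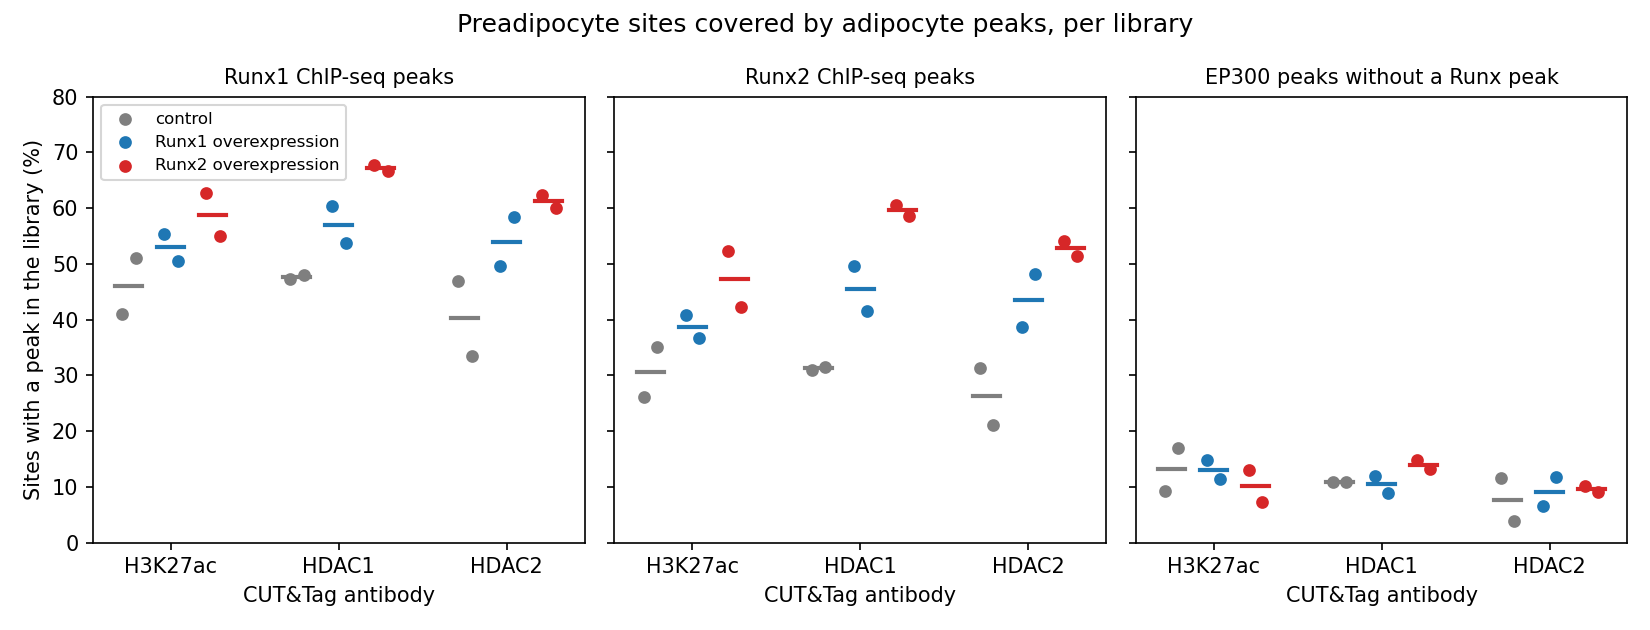
Percentage of preadipocyte Runx1 ChIP-seq peaks, Runx2 ChIP-seq peaks and EP300 peaks without a Runx peak that had a peak in each adipocyte library (points), with the mean of 2 libraries (lines). HDAC1 libraries covered 31.2% of Runx2 sites in controls and 59.6% with Runx2 overexpression, while coverage of the EP300 set ranged from 3.84% to 17.0% over all libraries.

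Regions were then called gained when both overexpressing libraries and neither control had a peak, and lost in the reverse case. Runx2 overexpression gained 6617 HDAC1 regions and lost 2010, gained 4754 HDAC2 regions and lost 995, and gained 2577 H3K27ac regions and lost 2891. Runx1 overexpression gained 2686 HDAC1 regions and lost 1780, gained 2763 HDAC2 regions and lost 699, and gained 2157 H3K27ac regions and lost 1601. The log2 ratio of gained to lost was 1.72 for HDAC1 with Runx2 and 0.59 with Runx1, 2.26 and 1.98 for HDAC2, and -0.17 and 0.43 for H3K27ac. Between single libraries, 1 from each group, it ranged from 0.78 to 1.05 for HDAC1 with Runx2 and from -0.0018 to 0.59 with Runx1. It ranged from -0.082 to 2.77 and from -0.90 to 3.20 for HDAC2, and from -1.79 to 1.31 and from -0.98 to 1.75 for H3K27ac. Equal list lengths gave ratios of 0.86 and 0.30 for HDAC1, 0.38 and 0.40 for HDAC2, and 0.18 and 0.054 for H3K27ac. Unchanged groups simulated with the HDAC1 list lengths of the Runx2 comparison gained 4254 and lost 969 regions on average, with more gains than losses. These counts can be too high, because each region kept its share of all 4 real libraries. The other splits of these libraries changed at most 1118 regions.

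Gained regions carried preadipocyte Runx peaks far more often than lost regions did, and not only those of the overexpressed factor. With Runx2 overexpression, a Runx2 peak lay at 26.1% of gained and 0.60% of lost HDAC1 regions, at 29.7% and 1.31% for HDAC2, and at 29.0% and 1.31% for H3K27ac. The odds ratios of gained against lost were 58.8 (95% interval 33.3 to 104), 31.9 (18.4 to 55.2) and 30.7 (22.0 to 42.8). With Runx1 overexpression, a Runx1 peak lay at 24% of gained and 3.15% of lost HDAC1 regions, at 26.5% and 4.15% for HDAC2, and at 15.9% and 3.0% for H3K27ac. Those odds ratios were 9.73 (7.35 to 12.9), 8.34 (5.70 to 12.2) and 6.10 (4.47 to 8.31). With peaks of the other factor they were 22.2 for HDAC1, 20.9 for HDAC2 and 5.55 for H3K27ac with Runx1 overexpression, and 17.2, 11.4 and 17.2 with Runx2 overexpression. Pooled lists lowered the odds ratios with the factor's own peaks to 4.80, 4.43 and 2.59 for Runx1 and to 23.2, 15.8 and 14.3 for Runx2, in the same order of antibodies. Regions are not replicates, so the intervals cover only the counting of regions. The 2 other ways to split the same 4 libraries gave odds ratios between 0.268 and 2.80 over the 6 comparisons. Regions found in all 4 libraries carried a Runx1 peak at 32.7% to 38.7%, above the gained regions of Runx1 overexpression. They carried a Runx2 peak at 18.0% to 19.3%, below the gained regions of Runx2 overexpression. Both contrasts turned with other choices, for HDAC1 and HDAC2 with Runx1 overexpression and for all 3 antibodies with Runx2 overexpression. With peaks of the other factor the odds ratio of gained regions against regions found in all libraries was 1.80 for HDAC1, 1.73 for HDAC2 and 0.892 for H3K27ac with Runx1 overexpression, and 0.506, 0.556 and 0.649 with Runx2 overexpression. For Runx2 overexpression the odds ratio of gained regions against regions found in all libraries was 0.527, 0.571 and 0.387 for H3K27ac, HDAC1 and HDAC2 with HA-Runx2 peaks, and 0.787, 0.681 and 0.767 with pooled lists. Without the second Runx2-overexpressing library it was 0.835, 0.856 and 0.937.

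**Figure D2:**
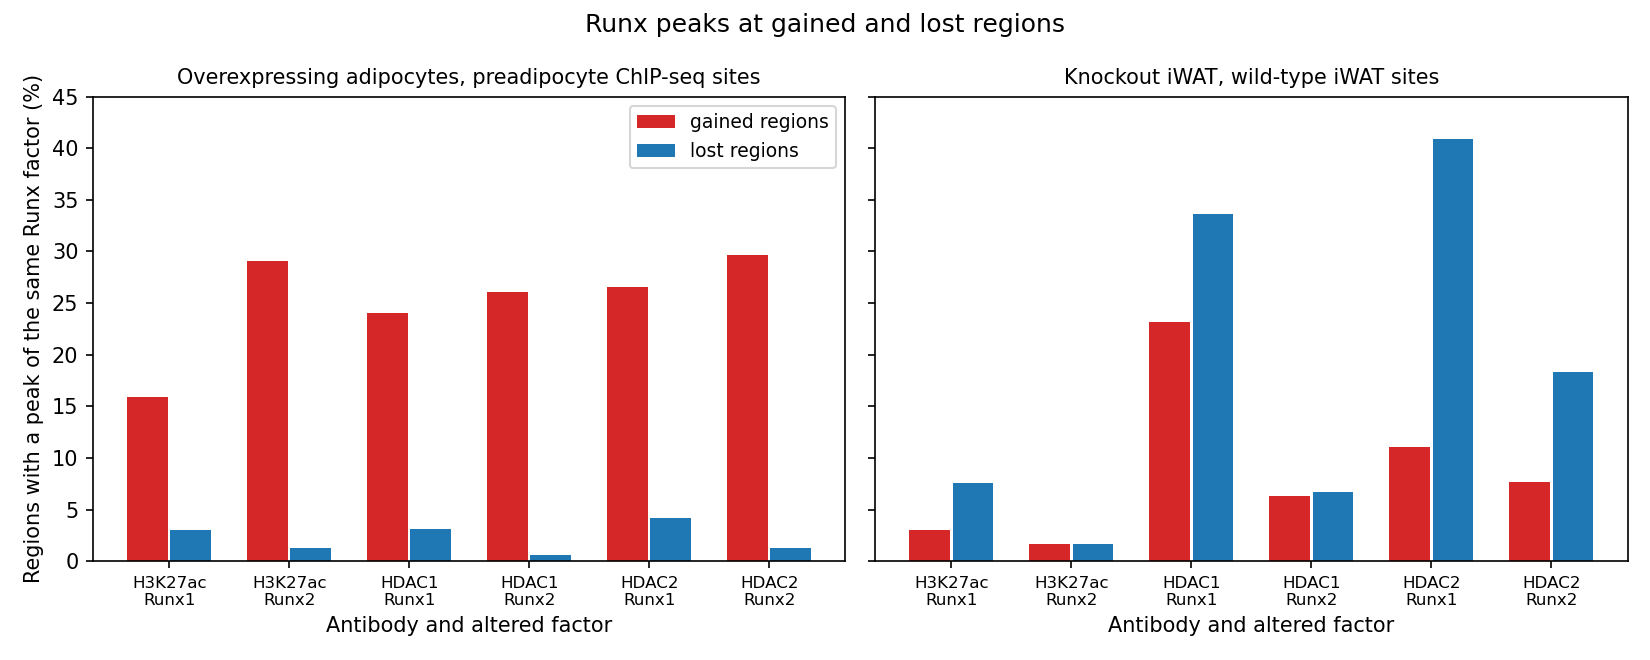
Percentage of gained (red) and lost (blue) regions with a peak of the same Runx factor, for overexpressing adipocytes against preadipocyte ChIP-seq peaks and for knockout iWAT against wild-type iWAT peaks. In the adipocytes 15.9% to 29.7% of gained regions and at most 4.15% of lost regions had such a peak.

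Among 100 kb windows, Runx2 overexpression gained 8 HDAC1 regions and lost 1 on chromosome 11 from 117800001 to 117900000, where it also gained 5 H3K27ac regions and lost 0. It gained 7 HDAC1 regions and lost 0 both on chromosome 11 from 8600001 to 8700000 and on chromosome 15 from 77200001 to 77300000, and chromosome 16 from 17900001 to 18000000 gained 6 HDAC2 regions and lost 1. Runx2 overexpression lost 6 H3K27ac regions on chromosome 12 from 32900001 to 33000000. Runx1 overexpression gained 5 H3K27ac regions on chromosome 11 from 98800001 to 98900000 and 4 HDAC1 regions on chromosome 4 from 107300001 to 107400000. It lost 5 HDAC1 regions on chromosome 12 from 100200001 to 100300000. Both overexpressing groups lost 4 HDAC1 regions on chromosome 13 from 47300001 to 47400000, where no region was found in all 4 libraries. No gene is named here, because the gene table in use is of another mouse assembly.

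With 2 libraries per group an exact test of the presence of a peak cannot call a single region, since its smallest two-sided p is 0.333. The count of changed regions was therefore set beside the 2 other splits of the same libraries. Runx2 overexpression changed 8627 HDAC1, 5749 HDAC2 and 5468 H3K27ac regions, against at most 1118, 1463 and 2373 in the other splits. Runx1 overexpression changed 4466 HDAC1, 3462 HDAC2 and 3758 H3K27ac regions, against at most 1481, 2766 and 2696. Lists of equal length gave 7378, 3032 and 5197 for Runx2 against at most 834, 522 and 882, and 4375, 2183 and 3123 for Runx1 against at most 1355, 639 and 1226. Single libraries weighed on these counts, because a region needs only 3 libraries once a library is left out. Without the first control H3K27ac library the log2 ratio with Runx1 became -2.17, and without either control HDAC1 library it became -1.02 or -1.05. Without the second control HDAC2 library it became -1.47 with Runx1 and -0.82 with Runx2, and without either Runx2-overexpressing H3K27ac library it became 0.08 or 1.69. The odds ratio for Runx1 overexpression fell to 1.45, 1.58 and 1.65 without the first H3K27ac, the first HDAC1 or the second HDAC2 library of the overexpressing cells. For Runx2 it stayed at 8.26 or more whichever library was left out.

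**Figure D3:**
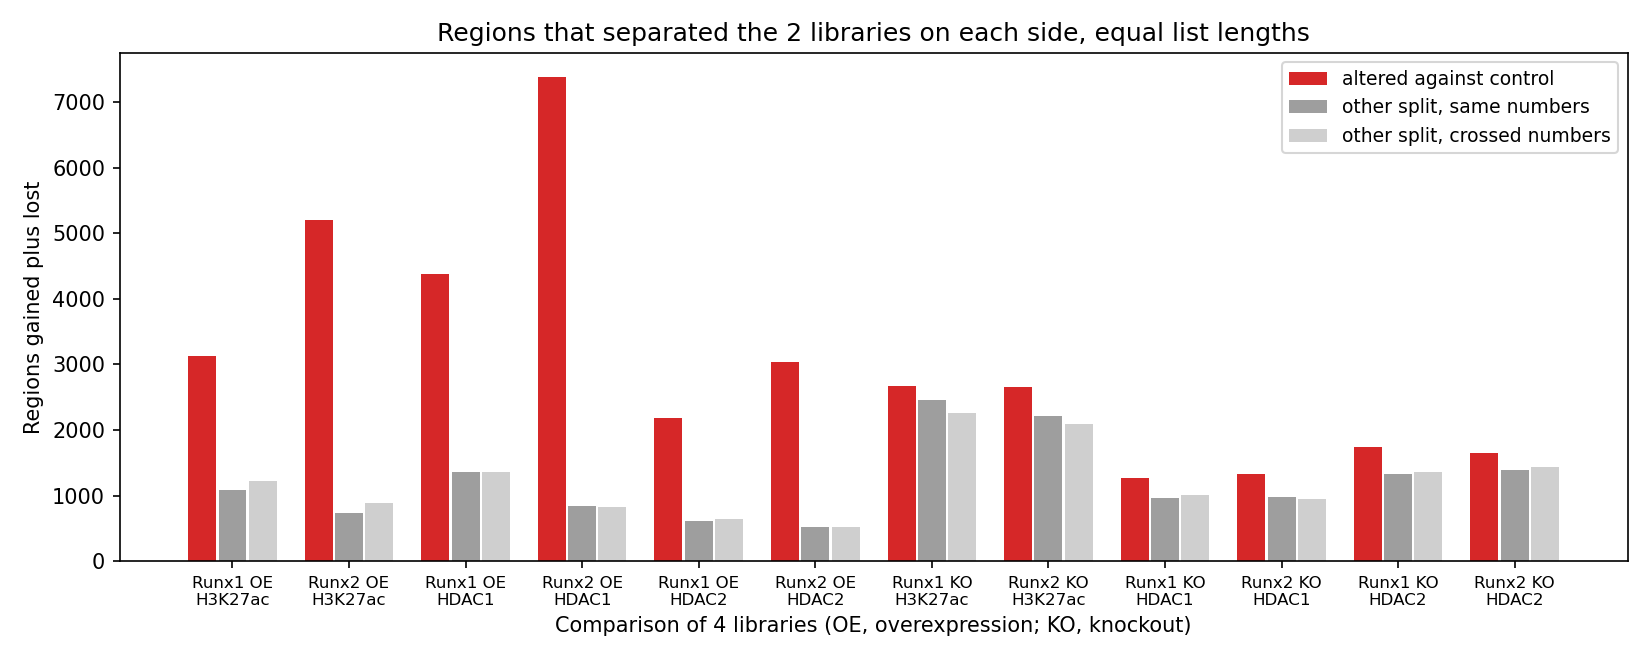
Number of regions gained plus lost when 4 libraries were divided into altered and control (red) or in the 2 other ways (grey), with lists of equal length. Overexpressing adipocytes reached 7378 changed HDAC1 regions with Runx2 against 834 in the other splits, and knockouts reached 1746 changed HDAC2 regions without Runx1 against 1358.

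The same regions were partly gained with several antibodies. Runx2 overexpression gained 730 regions with all 3 antibodies, and 383 of them (52.5%) had a Runx2 ChIP-seq peak. It lost 170 regions with all 3, of which 1 had a Runx2 peak. Runx1 overexpression gained 215 regions with all 3, 67 of them (31.2%) with a Runx1 peak, and lost 41, of which 0 had one. Of the HDAC2 regions gained with Runx2, 51.2% were also gained with HDAC1 and 20.9% with H3K27ac. With Runx1 overexpression these shares were 32.1% and 14.0%. The second HDAC1 library of Runx2 overexpression names HDAC2 in its antibody field. If that field is right, the overlap of HDAC1 with HDAC2 and the regions gained with all 3 antibodies would be affected. The strongest Runx2 peaks among the regions gained with all 3 antibodies lay on chromosome 10 from 76504626 to 76505372 (fold 21.6), chromosome 15 from 52791565 to 52792327 (fold 24.9) and chromosome 6 from 29326649 to 29327498 (fold 40.3). The chromosome 10 place was also gained with all 3 antibodies under Runx1 overexpression, where the Runx1 peak ran from 76504684 to 76505323 (fold 13.1). The strongest such Runx1 peak lay on chromosome 17 from 81198764 to 81199645 (fold 32.5).

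Runx1 and Runx2 overexpression changed many of the same regions. They shared 1840 gained HDAC1 regions, 1671 gained HDAC2 regions and 782 gained H3K27ac regions. Unchanged groups simulated against the same controls shared at most 673, 777 and 352 in 100 draws, and independent lists of these sizes would share 268, 247 and 83.2. Shared losses were 1133 for HDAC1, 470 for HDAC2 and 1220 for H3K27ac, against at most 479, 231 and 704 in the simulation and 53.9, 12.9 and 73.7 for independent lists. The excess over independent lists was smaller when each factor had 1 control library of its own, in both assignments. The shared regions then stay the same by construction, while independent lists would share 447 or 460 gained HDAC1, 527 or 638 gained HDAC2 and 215 or 259 gained H3K27ac regions. For losses they would share 835 or 844, 296 or 322, and 978 or 1071, so shared losses stood only 1.14 to 1.59 times above independence, and shared gains 2.62 to 4.12 times. Losses and gains cannot be compared in this way. A loss then needs a peak in 1 control library, while a shared loss still needs a peak in both.

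Knockout of Runx1 or Runx2 was compared with wild-type iWAT to ask what the loss of either factor changed in tissue. The deletion was directed at adipocytes, and the lists do not tell which cells of the tissue a site comes from. The mean coverage of wild-type Runx sites differed little between wild type and knockouts, while single antibodies moved in different directions. Wild-type H3K27ac already covered 90.8% of Runx1 sites and 94.8% of Runx2 sites, and HDAC1 89.7% of Runx2 sites, so the presence of a peak had little room to rise and these means cannot show changes of signal. Averaged over the 3 antibodies, 80.6% of 15818 iWAT Runx1 sites had a peak in wild type, 81.0% in Runx1 knockouts and 80.3% in Runx2 knockouts. At 10903 iWAT Runx2 sites the means were 89.6%, 90.3% and 89.7%. The 4 differences from wild type had exact permutation p-values from 0.454 to 0.870. HDAC2 coverage of Runx1 sites was 70.6% ± 0.55 (SD, n = 2) in wild type, 73.9% ± 1.9 in Runx1 knockouts and 70.7% ± 0.55 in Runx2 knockouts. In Runx2 knockouts H3K27ac coverage of Runx1 sites was 86.2% ± 1.3 against 90.8% ± 6.0 in wild type, and HDAC1 coverage was 83.9% ± 1.1 against 80.3% ± 3.1, each with n = 2. With equal list lengths the mean coverage of Runx1 sites was lower for all 3 antibodies in both knockouts. Runx1-site coverage in Runx1 knockouts then fell by 1.60 points (exact permutation p = 0.0370), with no adjustment over the settings tried. Without the second wild-type H3K27ac library, Runx2-site coverage in Runx1 knockouts was 1.42 points higher (exact permutation p = 0.0463). Without the first, Runx1-site coverage in Runx1 knockouts fell by 0.96 points; without the second, that in Runx2 knockouts was 1.07 points higher.

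Runx1 knockout gained 2824 HDAC2 regions and lost 333, and Runx2 knockout gained 1305 and lost 610. HDAC1 regions gained and lost numbered 899 and 551 without Runx1, and 1762 and 330 without Runx2. H3K27ac regions gained and lost numbered 1050 and 2010 without Runx1, and 292 and 4118 without Runx2. The log2 ratio of gained to lost HDAC2 regions was 3.08 for Runx1 and 1.10 for Runx2, and between single libraries it ranged from 1.28 to 1.63 and from 0.43 to 0.61. It was -3.82 for H3K27ac without Runx2, where single libraries gave -3.17 to -0.11. Equal list lengths took the HDAC2 ratios to 0.77 and 0.40 and the H3K27ac ratio without Runx2 to -0.49. Without Runx1 the H3K27ac balance then turned, with 1418 regions gained and 1259 lost, a log2 ratio of 0.17.

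The lost HDAC2 regions of Runx1 knockouts had an iWAT Runx1 peak at 40.8%, against 11.1% of the gained ones (odds ratio of gained against lost 0.181, 95% interval 0.141 to 0.231). Those of Runx2 knockouts had an iWAT Runx2 peak at 18.4%, against 7.66% (odds ratio 0.369, 0.276 to 0.493). For HDAC1 the odds ratio was 0.596 (0.471 to 0.753) without Runx1 and 0.941 (0.586 to 1.51) without Runx2. For H3K27ac it was 0.382 (0.259 to 0.563) and 1.01 (0.403 to 2.52). The other splits of the same HDAC2 libraries gave 0.618 and 0.742 for Runx1 and 0.921 and 1.12 for Runx2. Leaving out the first or second wild-type HDAC2 library turned the HDAC2 odds ratios to 1.05 or 1.37 for Runx1 and to 2.30 or 2.39 for Runx2. Omitting the second knockout library moved them the other way, to 0.0927 for Runx1 and 0.133 for Runx2. A region then needs only 1 library on that side, so these shifts partly follow from the rule. Without the first or second wild-type library the Runx1 knockout odds ratio turned to 2.41 or 3.50 for HDAC1 and to 1.23 or 2.06 for H3K27ac. Without the first or second library of the Runx2 knockouts their odds ratio was 0.176 or 0.286 for H3K27ac and 0.237 or 0.212 for HDAC1. Without a wild-type library it was 2.51 or 4.31 for H3K27ac and 3.23 or 6.66 for HDAC1.

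The knockouts changed more regions than both other splits of the same libraries, except H3K27ac without Runx1. That comparison exceeded them only with equal list lengths, and stood at 1609 against at most 2447 with -log10 q of 5 or more and at 3419 against at most 4694 with summit windows. With all peaks Runx1 knockouts changed 3157 HDAC2, 1450 HDAC1 and 3060 H3K27ac regions, against at most 1567, 1229 and 4257. Runx2 knockouts changed 1915, 2092 and 4410, against at most 1594, 1303 and 3445. With equal list lengths Runx1 knockouts changed 1746 HDAC2, 1270 HDAC1 and 2677 H3K27ac regions, against at most 1358, 1008 and 2450. Runx2 knockouts changed 1649, 1334 and 2656, against at most 1433, 982 and 2207. Leaving out a library reversed the log2 ratio for H3K27ac in Runx1 knockouts (0.54, 0.80 and 0.32 without the first or second knockout or the second wild-type library). It did so for HDAC1 in Runx1 knockouts (-1.42 and -0.55 without the first or second wild-type library) and in Runx2 knockouts (-0.25 without the first). HDAC2 in Runx2 knockouts turned to -0.82 and -0.91 without the first or second wild-type library.

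Chromosome 17 from 34800001 to 34900000 gained HDAC1 regions in both knockouts, with 4 gained and 1 lost without Runx1 and 5 gained and 0 lost without Runx2. Chromosome 4 from 130600001 to 130700000 lost HDAC2 regions in both, with 2 lost without Runx1, each with an iWAT Runx1 peak, and 3 lost without Runx2, of which 0 had an iWAT Runx2 peak. Runx1 knockouts gained 4 HDAC2 regions on chromosome 4 from 144900001 to 145000000, and Runx2 knockouts lost 6 H3K27ac regions on chromosome 8 from 85400001 to 85500000. Regions changed with all 3 antibodies numbered 1 gained and 1 lost for Runx1, and 1 gained and 0 lost for Runx2. Shared changes of the knockouts did not exceed those of simulated unchanged groups for any antibody or direction with all peaks. They shared 527 gained HDAC2 regions against a simulated mean of 578, and 1325 lost H3K27ac regions against 2031. Changed regions can enter such a simulation and raise its counts, so it cannot exclude shared changes. With 1 wild-type library for each knockout, independent lists would share 208 gained HDAC2 regions in either assignment and 1506 or 1911 lost H3K27ac regions, so shared gains then stood above independence and shared losses below it, as they did for all 3 antibodies. This contrast can follow from the rule, since a loss then needs a peak in only 1 wild-type library and a shared loss in both.

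Overexpression and knockout were compared region by region to ask whether places moved in opposite directions. Among 19730 HDAC2 regions present in both systems, 46 were lost with Runx1 overexpression and gained with Runx1 knockout, against 21.2 for independent lists (Fisher's exact test, adjusted p = 4.43e-06 over 24 tests). Regions gained in both numbered 116 against 86.7 (Fisher's exact test, adjusted p = 0.00366). For Runx2, 133 of 25618 H3K27ac regions were lost in both against 79.0 (Fisher's exact test, adjusted p = 6.43e-08), and 107 were gained with overexpression and lost with knockout against 81.0 (adjusted p = 0.00636). For HDAC1, 20 regions gained with Runx1 overexpression were lost with its knockout against 5.29 (Fisher's exact test, adjusted p = 3.58e-06). Over the 24 tests, 6 of 12 in the same direction and 8 of 12 in opposite directions had an adjusted p under 0.05, and 3, all in the same direction, lay below independence. Regions are not replicates. Regions with an unstable peak can change in either system, so lists can share more than independent ones without any effect. These p-values therefore cannot show that places moved in opposite directions.

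Full-length and IDR-deleted Runx2 were compared in preadipocytes to ask what the deleted part did to EP300 and HDAC2. EP300 had 70180 peaks with full-length and 59012 with IDR-deleted Runx2, and 24988 regions were found only with full length against 13632 only with the deletion. HDAC2 went the other way, with 50643 and 69881 peaks and 8645 regions only with full length against 28489 only with the deletion. At the 8822 Runx2 ChIP-seq sites EP300 coverage was 75.8% with full length and 74.6% with the deletion, and HDAC2 coverage was 69.9% and 79.0%. With equal list lengths HDAC2 coverage of those sites was 69.9% and 75.3%, while the small EP300 difference turned, to 74.5% and 74.6%. The log2 ratios of the single-condition regions then went from 0.87 to 0.02 for EP300 and from -1.72 to -0.08 for HDAC2. Each condition had a single list, so these differences have no replicate check.

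HA-tagged Runx2 was compared in its full-length and IDR-deleted forms in the same preadipocytes, with 2 libraries each. Of 29718 HA regions, 20697 (69.6%) were found in all 4 libraries. Full-length Runx2 alone had 1288 regions in both of its libraries, and IDR-deleted Runx2 alone had 298, a log2 ratio of 2.11. Between single libraries it ranged from 1.15 to 1.37. The other splits changed at most 618 regions, against 1586. With equal list lengths the counts were 840 and 763, a log2 ratio of 0.14. A Runx2 ChIP-seq peak lay at 31.1% of the regions found in all libraries, at 7.69% of those found only with full length and at 12.8% of those found only with the deletion. Without a library the log2 ratio lay between 1.36 and 1.83.

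In the authors' deposited table of changed HA sites, 163 of 172 sites were higher with full-length Runx2, with a median log2 fold of 0.65, and 9 were higher with the deletion, with a median of -0.46. The site with the lowest false discovery rate in the authors' deposited table lay on chromosome 14 from 57997875 to 57998275, with a log2 fold of 1.37 (FDR 7.96e-22). The next in the authors' deposited table was on chromosome 11 from 34956748 to 34957148, at 0.89 (FDR 3.68e-13). Among the sites higher with the deletion, the authors' deposited table placed chromosome 15 from 73026491 to 73026891 first, at -0.31 (FDR 0.00393). The authors' deposited lists for EP300 held 1338 depleted and 336 enriched peaks, and those for HDAC2 held 1251 depleted and 213 enriched peaks. None of the depleted EP300 peaks in the authors' deposited table lay in a region found only with the deletion and 252 lay in a region found only with full length, so depleted was read as lower with the deletion. For HDAC2 the authors' deposited table thus runs against the peak lists used above, since it held more depleted than enriched peaks while more regions were found only with the deletion, and this was not resolved. Of the depleted EP300 peaks in the authors' deposited table, 303 overlapped a depleted HDAC2 peak and 6 an enriched one. In the authors' deposited table the column read as a false discovery rate was under 0.05 for 1 depleted EP300 peak, 13 depleted HDAC2 peaks and 0 enriched peaks.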

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

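Coverage of preadipocyte Runx sites in overexpressing adipocytes kept its direction in every setting. The alternatives for the gained and lost regions, their Runx peaks, the peak overlaps and the equal lengths for shared changes were chosen before the data were examined. Odds ratios of gained against lost regions, HA-Runx2 sites, coverage of sites, the region-wise comparison of overexpression and knockout, leaving out libraries for shared changes and separate control libraries for them were chosen after the data were seen. Gene lists, their promoter and gene-body alternatives, gene-wise comparison of overexpression and knockout, and motif content were not run, because no mm39 gene table or genome sequence was used here. A count test of HA-tagged Runx2 was not run, because each library had counts for its own peaks only. Libraries left out change the rule itself, because a region then needs 1 library on that side. Every odds ratio of lost regions against regions found in all libraries stayed below 1. Those of gained regions in the knockouts did so too, so this was not particular to lost regions.

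With only peaks of -log10 q of 5 or more, gained regions numbered 1313 for H3K27ac with Runx1, 1605 for HDAC1 with Runx1, 1641 for HDAC2 with Runx1, 359 for H3K27ac without Runx1, 415 for HDAC1 without Runx1, 1373 for HDAC2 without Runx1, 75 for H3K27ac without Runx2, 946 for HDAC1 without Runx2 and 513 for HDAC2 without Runx2. Lost regions numbered 591 for H3K27ac with Runx1, 1028 for HDAC1 with Runx1, 308 for HDAC2 with Runx1, 1140 for H3K27ac with Runx2, 1209 for HDAC1 with Runx2, 491 for HDAC2 with Runx2, 1250 for H3K27ac without Runx1, 359 for HDAC1 without Runx1, 136 for HDAC2 without Runx1, 2477 for H3K27ac without Runx2, 192 for HDAC1 without Runx2 and 305 for HDAC2 without Runx2. The log2 ratio of gained to lost was 0.72 for H3K27ac with Runx2, 2.03 for HDAC1 with Runx2, 0.21 for HDAC1 without Runx1, 3.33 for HDAC2 without Runx1 and 0.75 for HDAC2 without Runx2. The Runx odds ratio of gained against lost was 0.746 for H3K27ac without Runx2 and 1.04 for HDAC1 without Runx2. Regions found with one Runx2 form only had a log2 ratio of full length over IDR-deleted of 1.28 for EP300 and -2.76 for HDAC2.

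With equal list lengths, gained regions numbered 1243 for HDAC2 with Runx1, 1715 for HDAC2 with Runx2, 1102 for HDAC2 without Runx1, 1104 for H3K27ac without Runx2 and 767 for HDAC1 without Runx2, and lost regions numbered 1259 for H3K27ac without Runx1, 644 for HDAC2 without Runx1, 1552 for H3K27ac without Runx2 and 567 for HDAC1 without Runx2. The log2 ratio was 0.18 for H3K27ac with Runx2, 0.86 for HDAC1 with Runx2, 0.38 for HDAC2 with Runx2, 0.17 for H3K27ac without Runx1, 0.20 for HDAC1 without Runx1, 0.77 for HDAC2 without Runx1, -0.49 for H3K27ac without Runx2, 0.44 for HDAC1 without Runx2 and 0.40 for HDAC2 without Runx2. Coverage of sites differed from control, in percentage points, by -1.60 for Runx1 knockouts at iWAT Runx1 sites, -0.563 for Runx1 knockouts at iWAT Runx2 sites, -0.318 for Runx2 knockouts at iWAT Runx2 sites, 0.659 for Runx2 against Runx1 knockouts at iWAT Runx1 sites, 0.245 for Runx2 against Runx1 knockouts at iWAT Runx2 sites, -1.28 for Runx1 overexpression at EP300 sites without Runx, -1.80 for Runx2 overexpression at EP300 sites without Runx and -0.515 for Runx2 against Runx1 overexpression at EP300 sites without Runx. Regions shared by the 2 factors numbered 668 for gained HDAC2 in adipocytes, 730 for lost HDAC2 in adipocytes, 268 for gained H3K27ac in iWAT, 551 for lost H3K27ac in iWAT, 172 for gained HDAC1 in iWAT, 226 for lost HDAC1 in iWAT, 254 for gained HDAC2 in iWAT and 303 for lost HDAC2 in iWAT. Log2 ratios of full length over IDR-deleted were 0.024 for EP300, -0.081 for HDAC2 and 0.14 for HA-tagged Runx2.

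With pooled lists, where a gained region needs a peak in 1 list and none in the other, gained regions numbered 21165 for H3K27ac with Runx1, 21908 for HDAC1 with Runx1, 19941 for HDAC2 with Runx1, 14317 for H3K27ac with Runx2, 26783 for HDAC1 with Runx2, 20351 for HDAC2 with Runx2, 13535 for H3K27ac without Runx1, 9660 for HDAC1 without Runx1, 20605 for HDAC2 without Runx1, 7350 for H3K27ac without Runx2, 16206 for HDAC1 without Runx2 and 15423 for HDAC2 without Runx2. Lost regions numbered 18604 for H3K27ac with Runx1, 17966 for HDAC1 with Runx1, 12306 for HDAC2 with Runx1, 23830 for H3K27ac with Runx2, 17719 for HDAC1 with Runx2, 13015 for HDAC2 with Runx2, 22308 for H3K27ac without Runx1, 6645 for HDAC1 without Runx1, 6645 for HDAC2 without Runx1, 30814 for H3K27ac without Runx2, 5266 for HDAC1 without Runx2 and 8257 for HDAC2 without Runx2. The log2 ratio was 0.60 for HDAC1 with Runx2, 0.64 for HDAC2 with Runx2, 1.63 for HDAC2 without Runx1, -2.07 for H3K27ac without Runx2, 1.62 for HDAC1 without Runx2 and 0.90 for HDAC2 without Runx2. The Runx odds ratio of gained regions against regions found in all libraries was 0.787 for H3K27ac with Runx2, 0.681 for HDAC1 with Runx2 and 0.767 for HDAC2 with Runx2, and of gained against lost it was 0.655 for H3K27ac without Runx2.

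Replicate numbers are the only sign of pairing. A replicate block, the mean over the 2 same-numbered pairs of single libraries, gave a log2 ratio of 0.91 for HDAC1 with Runx2, 1.46 for HDAC2 without Runx1, -1.64 for H3K27ac without Runx2, 1.19 for HDAC1 without Runx2 and 0.51 for HDAC2 without Runx2, and of 1.26 for HA-tagged Runx2. The mean over all 4 pairs of single libraries, matched or crossed and chosen after the data were seen, was 0.91 for HDAC1 with Runx2, 1.45 for HDAC2 without Runx1, -1.70 for H3K27ac without Runx2, 1.18 for HDAC1 without Runx2 and 0.51 for HDAC2 without Runx2, and 1.26 for HA-tagged Runx2. The block differed from that mean by -0.022 to 0.064. Both use 1 library per side, and each pair's ratio mostly follows its 2 list lengths. The 2 means are then close under any pairing, so this cannot tell whether pairing matters. Replicate differences correlated between -0.017 and 0.0621 over the 12 comparisons and at 0.005 for HA, so the numbers may be arbitrary.

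With peaks of the other factor, the Runx odds ratio of gained regions against regions found in all libraries was 0.892 for H3K27ac with Runx1, 1.80 for HDAC1 with Runx1, 1.73 for HDAC2 with Runx1, 0.649 for H3K27ac with Runx2, 0.506 for HDAC1 with Runx2 and 0.556 for HDAC2 with Runx2, and of gained against lost it was 0.370 for HDAC1 without Runx2. With HA-Runx2 peaks it was 0.527 for H3K27ac with Runx2, 0.571 for HDAC1 with Runx2 and 0.387 for HDAC2 with Runx2 against regions found in all libraries. Windows around summits gave 2.90 for H3K27ac without Runx2 and 0.663 for HDAC1 without Runx2 for gained against lost. Requiring a reciprocal overlap of 50% gave 34.1% for Runx1 ChIP-seq in Runx2, 44.0% for Runx2 ChIP-seq in Runx1, 43.7% for iWAT Runx1 in Runx2, 59.9% for iWAT Runx2 in Runx1, 54.4% for EP300 with full-length in IDR-deleted Runx2 and 67.6% for HDAC2 with full-length in IDR-deleted Runx2. The 5000 best peaks gave 48.6% for Runx1 ChIP-seq in Runx2, 48.8% for Runx2 ChIP-seq in Runx1 and 69.9% for iWAT Runx1 in Runx2.

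Leaving out each library in turn, gained regions ranged from 2598 to 11383 for H3K27ac with Runx1, 3601 to 10654 for HDAC1 with Runx1, 3039 to 12014 for HDAC2 with Runx1, 2904 to 10328 for H3K27ac with Runx2, 8070 to 15072 for HDAC1 with Runx2, 5098 to 11236 for HDAC2 with Runx2, 1458 to 6211 for H3K27ac without Runx1, 1422 to 5326 for HDAC1 without Runx1, 4331 to 10692 for HDAC2 without Runx1, 425 to 3606 for H3K27ac without Runx2, 2562 to 7891 for HDAC1 without Runx2 and 2246 to 6384 for HDAC2 without Runx2. Lost regions ranged from 2255 to 11668 for H3K27ac with Runx1, 2304 to 7823 for HDAC1 with Runx1, 875 to 8443 for HDAC2 with Runx1, 3192 to 14412 for H3K27ac with Runx2, 2594 to 7686 for HDAC1 with Runx2, 1313 to 9028 for HDAC2 with Runx2, 3562 to 23020 for H3K27ac without Runx1, 1164 to 3801 for HDAC1 without Runx1, 731 to 3408 for HDAC2 without Runx1, 5923 to 29838 for H3K27ac without Runx2, 768 to 3051 for HDAC1 without Runx2 and 1194 to 4282 for HDAC2 without Runx2. The log2 ratio ranged from -2.17 to 2.34 for H3K27ac with Runx1, -1.05 to 2.21 for HDAC1 with Runx1, -1.47 to 3.78 for HDAC2 with Runx1, -2.31 to 1.69 for H3K27ac with Runx2, 0.10 to 2.54 for HDAC1 with Runx2, -0.82 to 3.10 for HDAC2 with Runx2, -3.98 to 0.80 for H3K27ac without Runx1, -1.42 to 2.19 for HDAC1 without Runx1, 0.36 to 3.87 for HDAC2 without Runx1, -6.13 to -0.82 for H3K27ac without Runx2, -0.25 to 3.36 for HDAC1 without Runx2 and -0.91 to 2.42 for HDAC2 without Runx2. The Runx odds ratio of gained against lost ranged from 0.144 to 2.06 for H3K27ac without Runx1, 0.145 to 3.50 for HDAC1 without Runx1, 0.0927 to 1.37 for HDAC2 without Runx1, 0.176 to 4.31 for H3K27ac without Runx2, 0.212 to 6.66 for HDAC1 without Runx2 and 0.133 to 2.39 for HDAC2 without Runx2. Against regions found in all libraries it ranged from 0.835 to 1.69 for H3K27ac with Runx2, 0.856 to 1.49 for HDAC1 with Runx2 and 0.937 to 1.78 for HDAC2 with Runx2.

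With each library left out, coverage differences in percentage points ranged from -0.960 to 1.86 for Runx1 knockouts at iWAT Runx1 sites, 0.0210 to 1.42 for Runx1 knockouts at iWAT Runx2 sites, -1.75 to 1.07 for Runx2 knockouts at iWAT Runx1 sites, -0.570 to 0.824 for Runx2 knockouts at iWAT Runx2 sites, -1.01 to 1.59 for Runx1 overexpression at EP300 sites without Runx, -0.611 to 1.99 for Runx2 overexpression at EP300 sites without Runx, -0.561 to 1.36 for Runx2 against Runx1 overexpression at EP300 sites without Runx and 7.79 to 12.3 for Runx1 overexpression at Runx1 ChIP-seq sites. Shared regions ranged from 881 to 2866 for gained H3K27ac in adipocytes, 1273 to 9903 for lost H3K27ac in adipocytes, 2039 to 3524 for gained HDAC1 in adipocytes, 1292 to 6149 for lost HDAC1 in adipocytes, 1871 to 4691 for gained HDAC2 in adipocytes, 534 to 6807 for lost HDAC2 in adipocytes, 101 to 1122 for gained H3K27ac in iWAT, 1558 to 19882 for lost H3K27ac in iWAT, 430 to 1074 for gained HDAC1 in iWAT, 197 to 2284 for lost HDAC1 in iWAT, 751 to 1192 for gained HDAC2 in iWAT and 230 to 2720 for lost HDAC2 in iWAT. The log2 ratio for HA-tagged Runx2 ranged from 1.36 to 1.83.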

Other observations

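Most regions that overexpressing adipocytes gained carried EP300 in preadipocytes with full-length or IDR-deleted Runx2. No EP300 list without one of these Runx2 forms was available, so this is no baseline without them. An EP300 peak, with either Runx2 form, lay at 86.5% of the HDAC1 regions gained with Runx2, 46.9% of those lost and 98.1% of those found in all 4 libraries. With Runx1 the HDAC1 values were 80.2%, 57.2% and 96.4%. HDAC2 regions gained with Runx2 had EP300 at 92.4% and lost ones at 52.9%, and H3K27ac regions at 87.0% and 50.5%.

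Regions of knockout iWAT were also set beside the preadipocyte Runx sites. A Runx2 ChIP-seq peak lay at 7.21% of HDAC1 regions gained and 2.12% of those lost without Runx2 (odds ratio 3.58, 95% interval 1.66 to 7.74). A Runx1 ChIP-seq peak lay at 12.5% of HDAC1 regions gained and 7.44% of those lost without Runx1 (odds ratio 1.77, 1.22 to 2.57), and at 5.33% and 3.33% for H3K27ac (odds ratio 1.63, 1.14 to 2.35). For HDAC2 the odds ratio was 1.62 (1.05 to 2.50) without Runx1 and 1.18 (0.792 to 1.76) without Runx2. Gained regions thus had a larger share with a preadipocyte site than lost regions in 5 of the 6 comparisons, and H3K27ac without Runx2 had an odds ratio of 0.954 (0.525 to 1.73). The counts differ from the shares, since 56 gained and 67 lost H3K27ac regions had such a site without Runx1.

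The tests of unequal list lengths and the EP300 sites without Runx below were chosen only after the result was seen, and the bounds for the other tests were written down before their values were computed. Gained regions of overexpressing adipocytes overlapped preadipocyte Runx peaks more often than lost regions for all 3 antibodies and both factors. Longer lists of overexpressing cells could add regions of another kind, but with equal list lengths the lowest odds ratio of the 6 comparisons was 5.42. Regions already marked in preadipocytes could carry Runx more often, but among regions with EP300 the lowest lower 95% bound was 3.26. That EP300 was mapped only in preadipocytes with full-length or IDR-deleted Runx2, so marking without these forms was not seen. Stronger peaks could also carry Runx more often, but within classes of like peak strength the lowest Mantel-Haenszel odds ratio was 6.03. At EP300 sites without Runx, HDAC1 coverage with Runx2 overexpression was 3.15 points higher with all peaks, while it differed by -1.27 points with equal list lengths, where part of a fall is forced. With all peaks and Runx2 overexpression, HDAC2 coverage of these sites also rose, while H3K27ac coverage fell. Recruitment of HDAC1 and HDAC2 by Runx, and a return toward preadipocyte chromatin, general or limited to Runx sites, therefore both stay open.

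H3K27ac, a mark of active chromatin, and the deacetylases HDAC1 and HDAC2 gained some of the same regions with Runx2 overexpression. Of 10035 regions gained with any antibody, 730 were gained with all 3. H3K27ac was also gained at 18.2% of gained HDAC1 and 20.9% of gained HDAC2 regions. It was also lost at 29.8% of lost HDAC1 and 33.3% of lost HDAC2 regions, so sharing was not particular to gains. At gained regions the 3 could be recruited together, or open chromatin could be recovered with every antibody. The median Jaccard index between H3K27ac and deacetylase libraries of a group was 0.564, against 0.628 between replicates of an antibody (range 0.568 to 0.729) and 0.650 between HDAC1 and HDAC2. The test lay between its bounds, so open chromatin stays open as an explanation. A control library with an unspecific antibody would separate these.

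Lost HDAC2 regions of knockout iWAT overlapped Runx peaks more often than gained ones, which could mean loss of HDAC2 where Runx was bound. Unequal list lengths do not account for it, because the highest upper 95% bound with equal lengths was 0.445, and neither does peak strength, because the highest Mantel-Haenszel odds ratio was 0.341. With preadipocyte Runx peaks in place of wild-type iWAT peaks the highest upper bound was 2.50, with odds ratios of 1.62 (1.05 to 2.50) for Runx1 and 1.18 (0.792 to 1.76) for Runx2. This met the bound written for a technical source, in that the Runx peaks and the lost HDAC2 regions were both called in wild-type tissue. It cannot decide, because the preadipocyte sites come from other cells and another assay. iWAT peaks covered only 41.8% and 35.4% of those sites for Runx1 and 21.3% and 23.0% for Runx2. A true loss of HDAC2 at tissue Runx sites could be missed there, so both explanations stay open. Leaving out a wild-type HDAC2 library turned the direction, to 1.05 or 1.37 for Runx1, and leaving out the second knockout library gave 0.0927. A region then needs only 1 library on that side, so these values do not bear on the source.

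The second HDAC1 library of Runx2 overexpression carries HDAC2 in its antibody field. Its Jaccard index was 0.707 with the first HDAC1 library and 0.662 and 0.646 with the HDAC2 libraries. By the bound set beforehand this speaks against an HDAC2 antibody. After the values were seen it was judged not to decide, because the index does not place all other libraries with their own antibody. Runx1-overexpressing HDAC1 replicates had 0.605, below the 0.654 of an HDAC1 and HDAC2 pair, and HDAC2 replicates of every adipocyte group lay below the highest such pair. Control HDAC1 replicates had 0.729, above the 0.682 of the highest such pair, and HDAC1 replicates exceeded every such pair in all iWAT groups. Whether the field or the title is right could be told from the laboratory record.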
